A study of Mus musculus with 2 samples.

How the data were processed

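Total RNA from isolated mouse colonic epithelial cells was labelled with Hy5 using a miRCURY LNA kit, per the labels' protocols, and each of 2 samples was hybridised to 1 array in 1 colour. The group of each sample came from the agent named in its labels: control (n = 1) and DSS (n = 1). Whether cells of several mice were pooled, the array's maker and the software that read the spots are not given in the sources used here.

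The deposited scanner files hold, for each of 3200 spots, the median spot intensity and a median background intensity, and per the file headers the values combine scans at 3 gains. The authors' deposited value table holds 1 processed intensity per probe and array on a linear scale, and no source used here says how it was made. It was rebuilt from the spot intensities: each listed value equals the spot intensity minus the mean of the blank spots, times 0.563 on the control array and 0.787 on the DSS array. The blank mean leaves out the 45 highest and 45 lowest of 896 blank spots. Listed values have a median of 25 on both arrays, probes at or below the blank mean plus 2 SD are left empty, and the largest deviation from this rule was 4.0e-06. Scale, centring and array of origin of both columns are thereby known.

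Measured miRNAs were those above the trimmed blank mean plus 2 SD. The trimmed blank mean was 92.7 (SD 3.49) on the control array and 121.8 (SD 4.53) on the DSS array. This gave the same probes as the authors' table. Of the 1900 mouse miRNA probes 12 name several miRNAs and stand for each of them, and 1 probe (miR-3081-3p) with a poor quality flag was left out. Control spots entered the background fit only. The median intensity over blanks among measured probes was 44.4 on the control and 31.8 on the DSS array, so that many miRNAs lie close to the limit.

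Spot intensities were corrected with limma's normexp model (limma 3.58.1, R 4.3.3) with an offset of 50, fitted on all spots, then log2 transformed and quantile normalised over the miRNA probes. The files' background value was not subtracted, because it followed the brightness of the spot itself: Spearman's rho between both across spots was 0.880 on the control and 0.699 on the DSS array, and in spots brighter than 1000 it amounted to a median of 84.2% and 73.4% of the spot. Its subtraction, below called subtraction of the background around each spot, was run as an added alternative. What this value covers is not given in the sources used here, and its subtraction may remove signal. Each group holds 1 array, so the difference between the groups was not tested and has no p-value or standard error, and a difference is counted at 2-fold or more among miRNAs measured on both arrays. For a miRNA measured on 1 array only, a lower bound was formed from its normalised value and the higher of the dim probe's own value and the lowest value measured on that array.

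For lists of miRNAs, the median log2 difference of members measured on both arrays was placed among 10000 random lists of the same size drawn within 20 brightness bins, for lists with at least 3 such members. The 19 lists were epithelial (miR-200 family, miR-203, miR-205 and the miR-183 cluster), intestinal epithelial, leukocyte, erythroid, smooth muscle and fibroblast, endothelial, neural, liver and pancreas, inflammation-induced, miR-17-92 and paralogous clusters, let-7, miR-34, miR-29, miR-30, miR-15/16, miR-23/24/27, hypoxia-induced, miR-221 with miR-222, and miR-26. The lists, the main settings and most of the other settings were fixed before the data were examined. So was the rule for naming miRNAs: list members brighter than the median or 2 to 4 examples per list, the 10 largest differences each way among miRNAs brighter than the median, the 3 brightest miRNAs measured on a single array, and the 5 brightest of each array.

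The procedure was tested on simulated arrays with known changes among the 1900 probes of this comparison. Among miRNAs brighter than the median a true log2 difference of 2 was estimated at 1.32 (median) and passed 2-fold in 79.5% of cases, and a true −2 was estimated at −1.28 and passed in 90.5%. A true difference of 1 was estimated at 0.61 and passed in 0%, a true −1 at −0.81 and passed in 21.7%, and unchanged miRNAs passed in 0%. The offset thus compresses folds. The simulated noise was the spread of spike control spots within an array and that of the blanks. Differences between animals, cell isolations or hybridisations were not simulated, so the 0% for unchanged miRNAs is no rate of false calls here. When only the let-7 list was shifted, by a log2 difference of 1, it lay at the 100 percentile. Of the 9 other lists, 1 fell outside the central 95% of random lists.

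Alternatives covered the scaling between arrays (median, 75th percentile, none, cyclic loess), the background correction (blank subtraction, offset 0, none), the authors' values, filters on dim probes, the detection limit and the fold threshold. Scaling to the spike control spots and subtraction of the background around each spot were added after the data were seen. Names of neighbouring miRNA genes came from a RefSeq gene table of assembly GRCm38.p6, in which 1818 of the 1900 probes matched a single gene; the files name no genome build, so no coordinates are given. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.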

Results

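Small RNA was profiled in colonic epithelial cells isolated from C57BL/6 mice aged 8 weeks. The design set an untreated control against colon inflammation induced with dextran sulfate sodium (DSS), a sulfated polysaccharide that injures the colonic epithelium, given at 2.5% in the drinking water for 5 days. Each condition was represented by 1 array (control n = 1, DSS n = 1), on which total RNA labelled with the fluorescent dye Hy5 was hybridised to 1900 probes for mouse miRNAs. With 1 array per condition no difference below has a replicate check, and the number of arrays limits the precision. All differences are given on the log2 scale as DSS minus control after background correction with an offset and quantile normalisation, which shrinks folds of dim miRNAs.

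The control array measured 1070 miRNA probes above the blank spots (56.3%) and the DSS array 1169 (61.5%). Both arrays measured 995 probes, 174 were measured on the DSS array only, 75 on the control array only and 656 on neither. The mean of the Negative Control 3 spots passed the same limit on both arrays, at 13.2 (control) and 9.58 (DSS) over blanks. That of Negative Control 1 passed it on the DSS array only (15.8). A probe counted as measured near the limit may thus hold no more signal than these control spots. The brightest 5 miRNAs were the same on both arrays, namely miR-6538, miR-5126, miR-3154, miR-6240 and miR-3960. The normalised difference was −0.49 for miR-5126 and 0.49 for miR-6240, which exchanged ranks, and 0.00 for miR-6538, miR-3154 and miR-3960, which held the same rank on both arrays. Quantile normalisation gives equal ranks equal values, so these differences follow from rank alone. In the authors' values they were 0.003 for miR-5126, 0.99 for miR-6240, 0.23 for miR-6538, 0.44 for miR-3154 and −0.24 for miR-3960. Across the 995 miRNAs measured on both arrays, which are not independent replicates, Pearson's r between the arrays was 0.975, and the central 95% of differences ran from −0.76 to 0.65. Spike control spots, which carry no miRNA probe, were 2.05-fold (Spike Control 1) and 1.88-fold (Spike Control 2) brighter over blanks on the DSS array.

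The largest differences after quantile normalisation were decreases, although in the authors' values miR-150-5p (3.04) moved further up than miR-714 down (−2.90). miR-714 was 4.90-fold lower on the DSS array (log2 difference −2.29) and miR-99b-5p 4.04-fold lower (−2.02). miR-99b-5p is processed from a cluster that also yields let-7e and miR-125a. Those mature miRNAs differed by −0.15 for let-7e-5p and 0.10 for miR-125a-5p, both near the detection limit, and by −0.32 for miR-125a-3p. The other arm of the miR-99b hairpin, miR-99b-3p, was measured on the control array only (−0.15). miR-6956-5p (−1.35), miR-486b-3p (−1.21) and miR-92a-2-5p (−1.16), the passenger strand of a member of the miR-106a-363 cluster, were lower as well. A further 5 miRNAs were just over 2-fold lower, with differences of −1.10 for miR-7224-5p, miR-5621-5p and miR-7030-5p, −1.07 for miR-5623-5p and −1.06 for miR-6922-5p. All 10 stayed lower under each scaling between the arrays, although scaling to the spike controls lowers every unscaled difference and could not have raised them. Subtracting the files' background value around each spot gave 1.28 for miR-714, 0.23 for miR-92a-2-5p and 0.11 for miR-5623-5p. After that subtraction only 1 of the 10, miR-5621-5p (−1.96), passed 2-fold.

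On the higher side, miR-5119 was 3.11-fold brighter on the DSS array (1.64) and miR-7686-5p 2.71-fold (1.44). miR-150-5p, a miRNA of mature lymphocytes that targets the transcription factor Myb, was 2.09-fold higher (1.07), as was miR-690 (1.07), and miR-5100 was 2.05-fold higher (1.03). Under 2-fold but still among the 10 largest were miR-6238 (0.97), miR-7005-5p (0.92), miR-6907-5p (0.91), miR-125b-5p (0.91) and miR-6351 (0.85). On the control array miR-150-5p lay near the detection limit of 99.6, with a brightness of 106.3. Negative Control 3 spots had a mean of 105.8 there, so the fold of miR-150-5p is poorly determined. In the authors' table miR-150-5p went from 7.68 to 63.4 and miR-5119 from 167 to 460, while miR-99b-5p went from 414 to 57.3 and miR-714 from 1001 to 134. These increases depend on the scaling: relative to the spike control spots, a scaling chosen after the data were seen that moved the median of all miRNAs measured on both arrays to −1.02, only miR-7686-5p of the 10 stayed higher (0.08). Subtracting the background around each spot turned miR-690 to −1.50 and miR-6907-5p to −0.43 and left miR-5119 at 0.28, miR-7686-5p at 0.66, miR-150-5p at 0.23 and miR-5100 at 0.52, so that 0 of the 5 passed 2-fold.

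**Figure D1:**
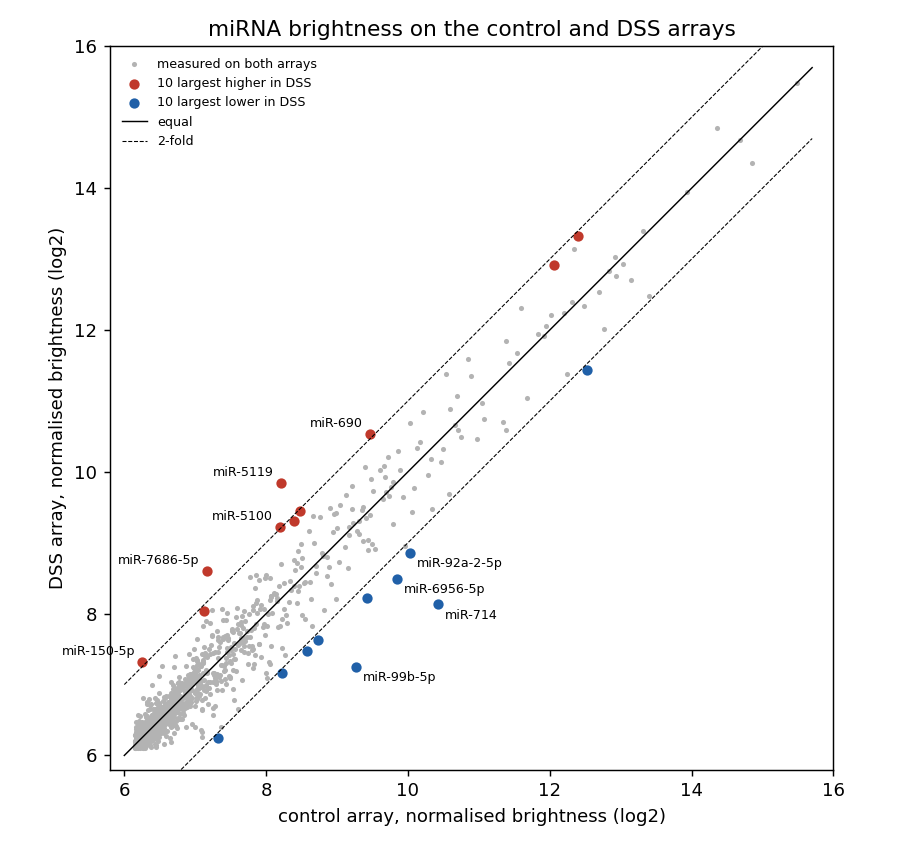
Normalised brightness (log2) of the 995 miRNAs measured on both arrays, control array on the horizontal and DSS array on the vertical axis, 1 point per miRNA, with lines of equality and of 2-fold difference. The 10 largest higher (red) and 10 largest lower (blue) miRNAs among those brighter than the median are coloured, from 1.64 for miR-5119 to −2.29 for miR-714; with scaling to the spike control spots only 1 of the 10 red points, miR-7686-5p, would stay above equality.

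In total 5 miRNAs were at least 2-fold higher and 10 at least 2-fold lower, among the 995 measured on both arrays. The balance between the directions depends on the scaling: 2 were higher and 42 lower with median scaling, 2 and 41 with 75th percentile scaling over all probes, 3 and 17 with that percentile over the miRNAs measured on both arrays, 1 and 51 with no scaling, and 0 and 549 with scaling to the spike controls. The authors' table, which carries no offset, held 89 miRNAs at least 2-fold higher and 41 at least 2-fold lower, with a median difference of 0.21. On that scale, 3 of the 5 higher and all 10 lower miRNAs passed 2-fold. Of the 35 named miRNAs brighter than the median that were higher on the DSS array, 30 stayed higher with median scaling, 31 and 34 with the 2 percentile scalings, 28 with no scaling and 1 with scaling to the spike controls.

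Epithelial miRNAs formed 2 lists. The miR-200 family, which restrains the ZEB repressors of E-cadherin, and miR-203, miR-205 and the miR-183 cluster formed a list of 10, of which 5 were measured on both arrays. All 5 were higher on the DSS array, with 0.68 for miR-200c-3p, 0.37 for miR-205-5p and 0.20 each for miR-200a-3p and miR-200b-3p, the last at −0.31 with no scaling. Their median was 0.22, at the 97.1 percentile of random lists matched on brightness and inside their central 95%, and it was −0.80 with scaling to the spike controls, where it lay 0.22 above the median of all miRNAs. It lay at the 98.6 percentile in the authors' table and at 99.7 with scaling by 1 factor per array. After subtraction of the background around each spot it lay at 88.5. A single factor adds the same amount to every log2 difference. All such scalings, the spike controls included, thus share 1 percentile per list and count as 1 result. Of the miRNAs abundant in differentiated gut epithelium, 3 of 4 measured members were higher: miR-194-5p (0.55), miR-192-5p (0.45) and miR-215-5p (0.43). miR-375-3p, of endocrine cells, was at −0.005. The median of this list was 0.44, at the 99.6 percentile, but −0.90 with scaling to the spike controls, where it lay 0.12 above the median of all miRNAs, and −0.006 (48.9 percentile) after subtraction of the background around each spot. Its percentile was 90.9 in the authors' table and 88.1 with each scaling by 1 factor per array.

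Leukocyte and erythroid miRNAs measured on both arrays were also higher on the DSS array, except with scaling to the spike controls and, for part of them, with subtraction of the background around each spot. miR-150-5p (1.07), miR-223-3p (0.24), a miRNA of granulocytes and monocytes, and miR-342-3p (0.15) were the 3 of 7 leukocyte miRNAs measured on both arrays. Their median of 0.24, the value of miR-223-3p, lay at the 99.1 percentile and was 1.28 in the authors' table. On the control array these 3 lay at 13.7, 17.4 and 20.1 over blanks, against 13.2 for the Negative Control 3 spots. Their folds are thus poorly determined. The median turned to −0.70 with scaling to the spike controls, where it lay 0.32 above the median of all miRNAs (99.7 percentile). It turned to −0.08 (23.4 percentile) with subtraction of the background around each spot. miR-142a-5p was measured on the DSS array only, and 3 members on neither array. The red cell miRNA miR-451a differed by 0.73 and the probe shared by miR-486a-5p and miR-486b-5p by 0.19, against −0.39 and −0.91 with scaling to the spike controls and 0.28 and −0.03 with subtraction of the background around each spot. Too few erythroid miRNAs were measured for a list median.

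The let-7 family comprises miRNAs that accumulate in differentiated cells. Of 8 members measured on both arrays 6 were higher (relative to the spike controls, let-7b-5p was at −0.68), led by let-7b-5p (0.66), let-7d-5p (0.63), let-7c-5p (0.47) and let-7a-5p (0.41), while let-7e-5p (−0.15) and let-7g-5p (−0.11) were lower. The family's median was 0.28 (99.9 percentile), but −0.82 with scaling to the spike controls, where it lay 0.20 above the median of all miRNAs (99.6 percentile), and 0.02 (58.7 percentile) after subtraction of the background around each spot. In the miR-30 family miR-30d-5p (0.54), miR-30c-5p (0.36) and miR-30b-5p (0.20) were higher and miR-30a-5p was lower (−0.19). miR-30e-5p was measured on the control array only (−0.12), so 4 of 5 members entered the family's median. That median was also 0.28 (99.5 percentile), and −0.87 with scaling to the spike controls, where it lay 0.15 above the median of all miRNAs; its percentile was 96.5 in the authors' table, 96.1 with each scaling by 1 factor per array and 80.5 after subtraction of the background around each spot. Probes of 1 family detect near-identical sequences, so their members are not independent measurements.

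miRNAs induced by NF-kB or cytokine signalling were mostly out of reach. Of 10 listed, 7 were measured on neither array, miR-155-5p, miR-146a-5p, miR-146b-5p and miR-31-5p among them. miR-21a-5p, a target of STAT3, differed by 0.19, miR-223-3p by 0.24 and miR-212-3p by −0.11, with a median of 0.19 (95.4 percentile) that turned to −0.02 with no scaling and −0.99 with scaling to the spike controls. Its percentile was 44.2 in the authors' table and 39.2 with each scaling by 1 factor per array. The hypoxia-induced miR-210-3p differed by 0.33.

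Among mesenchymal miRNAs the differences were mixed. The smooth muscle and fibroblast list had 6 of 8 measured members higher and a median of 0.09 (82.6 percentile), which was −0.09 with median scaling, −0.08 with 75th percentile scaling over all probes, −0.18 with no scaling and −1.15 with scaling to the spike controls. miR-125b-5p (0.91) and miR-145a-5p (0.44) stood highest, while miR-143-3p, transcribed together with miR-145a, differed by 0.06 and miR-133b-3p by −0.23. With no scaling miR-145a-5p was at −0.23, and after subtraction of the background around each spot at 1.31. Of the endothelial list only miR-126a-3p was measured on both arrays (−0.06). The neural list had miR-129-5p on both (−0.06) and miR-128-3p on the DSS array only. No member of the liver and pancreas list was measured on both arrays: miR-122-5p and miR-216a-5p were above the limit on the DSS array only and miR-217-5p on the control array only.

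The remaining families lay inside the central 95% of random lists after quantile normalisation. The proliferation-associated miR-17-92 and paralogous clusters had a median of 0.02 (78.0 percentile), with 4 members higher and 3 lower, from miR-106a-5p at 0.13 to miR-17-5p at −0.15. The miR-15/16 family had a median of 0.18 (95.7 percentile) and was led by miR-15b-5p (0.55). Outside this median, miR-195a-5p was measured on the control array only (−0.19) and miR-497a-5p on the DSS array only (0.03). The list's percentile was 99.2 in the authors' table (median 1.30), 99.3 with blank subtraction, 97.8 with cyclic loess and 98.2 with each scaling by 1 factor per array. That 1.30 is the value of miR-15a-5p, at 7.29 (control) and 12.8 (DSS) over blanks. Negative control spots reached 13.2 (control) and 15.8 (DSS), so it is poorly determined. For the miR-29 family the median was 0.10 (87.3 percentile), and for the miR-23/24/27 clusters 0.12 (75.1 percentile), where miR-23b-3p (0.69) and miR-23a-3p (0.51) were higher and the bright miR-24-3p was at 0.00. With no scaling the median of the miR-23/24/27 list was −0.06 and miR-24-3p was at −0.49. miR-24-3p was at 3.465 after subtraction of the background around each spot and at −1.46 with scaling to the spike controls. After subtraction of the background around each spot the miR-29 list lay at the 99.4 percentile and the miR-23/24/27 list at 100. With scaling to the spike controls each of these 4 medians was below 0, between −0.80 and −1.03. miR-26a-5p differed by 0.45 and miR-221-3p by −0.11. Their partners were measured on 1 array only, miR-26b-5p on the control array (−0.06) and miR-222-3p on the DSS array (0.23). Of the p53-induced miR-34 family miR-34a-5p and miR-34b-5p were measured on the DSS array only.

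Of the 19 lists, 11 had at least 3 miRNAs measured on both arrays. The medians of 4 lists (let-7, intestinal epithelial, leukocyte and miR-30) lay above the central 95% of 10000 random lists after quantile normalisation, and 0 lay below it. Which lists did so depends on the scaling. With scaling by 1 factor per array, which gives the same percentiles whatever the factor, these were let-7 (99.6 percentile), leukocyte, epithelial miR-200 and miR-15/16. These percentiles describe this pair of arrays and are no test across animals.

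**Figure D2:**
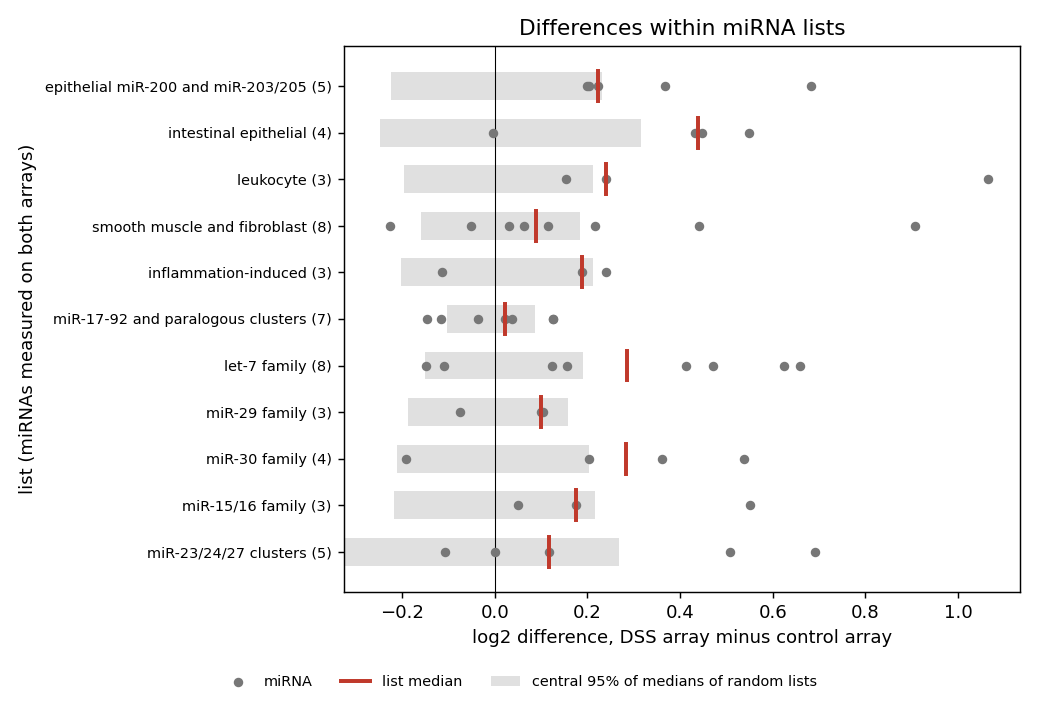
Log2 differences (DSS minus control, horizontal axis) of the miRNAs in the 11 lists with at least 3 members measured on both arrays; points are miRNAs, red lines list medians, and grey bars the central 95% of medians of random lists matched on brightness. The let-7, intestinal epithelial, leukocyte and miR-30 medians (0.28, 0.44, 0.24 and 0.28) lie right of their bars, while with scaling to the spike control spots all 11 medians fall below 0, as the median of all miRNAs does (−1.02).

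miRNAs measured on a single array were dim. The brightest of the DSS array alone were miR-204-5p, miR-3078-3p and miR-15b-3p, and of the control array alone miR-219a-1-3p, miR-7010-5p and miR-6922-3p. With the offset, none of these probes reached a lower bound of 1.5-fold: the highest bound was at least 1.25-fold for the DSS array and at least 1.35-fold for the control array. The offset shrinks the folds of such dim probes. In the authors' values, which carry no offset, miR-204-5p was 20.1 on the DSS array, against a lowest listed control value of 3.94. miR-219a-1-3p was 17.9 on the control array, against a lowest listed DSS value of 7.14. With the detection limit at 3 SD in place of 2 SD above the blanks, the DSS array alone measured 72 and the control array alone 114, which turns the balance between them.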

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

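The tests on the spike spots, on DSS treatment, on the leukocyte list alone and on miR-99b-5p were chosen after the result was seen, while those on the 4 list medians among low-numbered miRNAs and after cyclic loess were written before it.

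Of 11 sets of control spots above the detection limit on both arrays, 6 were brighter on the DSS array with no overlap between spots. The log2 ratio of blank-subtracted brightness, DSS over control, was 1.04 for Spike Control 1, 0.91 for Spike Control 2, 0.99 for S-Probe1, 1.19 for S-Probe26, 1.12 for S-Probe27 and 1.07 for S-Probe28, each from 8 spots per array. The amounts of these controls and what each S-Probe detects are not given in the sources used here. S-Probe6 went the other way (−2.28), and the dim sets were at −0.46 for Negative Control 3, −0.28 for S-Probe7, 0.19 for QC-Probe and 0.79 for S-Probe2.

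A brighter array as the only cause is argued against, because the median of the same ratio over the miRNAs measured on both arrays was −0.27. The mean for both Spike Control sets was 0.97. A brighter array that held less small RNA would give both values and stays open. The blanks were brighter on the DSS array as well, at 121.8 against 92.7. A single lower amount of every small RNA on the DSS array is argued against only where brightness is proportional to amount. The ratio differed by −0.29 between the brightest 249 miRNAs (median −0.62) and the 248 next brightest (−0.33). The standard error was 0.068 across miRNAs, which are not independent. Whether the response to amount differed between the arrays was not tested, so a single lower amount stays open. Unequal spike amounts were not tested and stay open, as does the hypothesis of a lower small RNA yield after DSS that differs between miRNAs, which 1 array per group cannot decide. The measure bears on the increases given above, since scaling to these spots left 1 of the 35 named higher miRNAs brighter than the median above 0, while all 12 named lower ones stayed lower. With no scaling all 12 were lower already, and spike scaling lowers every unscaled difference by the same amount. That they stayed lower was thus fixed beforehand and gives the decreases no support. The 10 largest differences each way were also chosen from these same values.

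The medians of the let-7, intestinal epithelial, leukocyte and miR-30 lists were higher on the DSS array than brightness-matched random lists. A shift shared with the low-numbered miRNAs outside the 19 lists is argued against for let-7, intestinal epithelial and miR-30. After quantile normalisation these 3 of the 4 lists stayed above the central 95% of random lists drawn from 173 such miRNAs numbered 500 or lower. The leukocyte list, at 93.75, did not, and for it such a shift stays open. Because these random lists held no listed miRNA, a shift shared by the listed miRNAs stays open too. Every list median was above 0, from 0.02 (miR-17-92) to 0.44 (intestinal epithelial). For a brightness trend between the arrays, all 4 lists stayed above that range after cyclic loess, but quantile normalisation and matching on brightness had already removed such a trend and loess moved the medians by under 0.05, so this decides nothing; with each scaling by 1 factor the intestinal (88.1) and miR-30 (96.1) lists fell inside the range. An effect of DSS treatment cannot be told apart from a difference between animals, cell isolations or arrays, with 1 array per group. Subtraction of the background around each spot left the medians at 0.02, −0.006, −0.08 and 0.04. That value followed the brightness of the spot itself, so its subtraction may remove signal and decides nothing here. Near-identical probes within families keep a technical origin open as well.

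miR-99b-5p was 4.04-fold lower on the DSS array. If lower transcription of its cluster acted equally on its mature miRNAs, let-7e-5p and miR-125a-5p would have dropped nearly to the blanks; the nearer of them exceeded that brightness by 3.73 blank SDs and the other by 5.70. Both are past the bound of 3 blank SDs, but they lay only 8.66 and 6.84 blank SDs above the blanks on the control array, where a requirement of 10 was added after these values were seen; as miRNAs this near the limit exclude little, and let-7e-5p may take up signal from other let-7 members, this decides nothing. miR-125a-3p (−0.32) and miR-99b-3p, measured on the control array only, were lower too and took no part in this comparison. A defect of 1 spot is equally open, as each array carries 1 spot of the miR-99b-5p probe. The difference was −0.73 after subtraction of the background around each spot and −2.85 in the authors' table.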

How the results depend on the processing

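Scaling to the spike control spots and subtraction of the background around each spot were chosen after the data were seen. Of 689 values of 53 named miRNAs under the alternatives, 568 moved by under 1.5-fold, 113 by more, and 8 of miRNAs past 2-fold changed sign. The filters on dim probes cannot change these values, and their unchanged values count among the 568. Counts of 2-fold higher and lower miRNAs (5 and 10) were 2 and 42 with median scaling, 2 and 41 with 75th percentile scaling over all probes, 3 and 17 over the miRNAs measured on both arrays, 1 and 51 with no scaling, 120 and 19 with blank subtraction, 16 and 25 with offset 0, 3 and 6 with no background correction, 89 and 41 in the authors' values, 0 and 549 with spike scaling, 21 and 21 with subtraction of the background around each spot, 32 and 42 at 1.5-fold and 1 and 2 at 3-fold. Cyclic loess gave 4 and 12, and the filters on dim probes and the detection limits 5 and 10. With the limit at 3 SD, 72 miRNAs were measured on the DSS array only and 114 on the control array only. The median of all miRNAs moved to −1.02 with spike scaling, 0.43 with blank subtraction, 0.28 with 75th percentile scaling over miRNAs measured on both arrays and 0.21 in the authors' values. Blank subtraction was followed here by quantile normalisation, without which the median was −0.27. List medians with blank subtraction were 1.002 (epithelial), 1.029 (intestinal), 1.337 (leukocyte), 1.037 (let-7) and 1.025 (miR-15/16). In the authors' values the list medians were 1.285 (leukocyte, the value of the dim miR-223-3p), 0.615 (miR-17-92) and 1.296 (miR-15/16, the value of the dim miR-15a-5p). With spike scaling they were −0.799 (epithelial), −0.900 (intestinal), −0.700 (leukocyte), −1.151 (smooth muscle and fibroblast), −0.988 (inflammation-induced), −0.885 (miR-17-92), −0.823 (let-7), −0.937 (miR-29), −0.872 (miR-30), −0.798 (miR-15/16) and −1.032 (miR-23/24/27), and miR-5119 was at −0.107, miR-150-5p at −0.011, miR-690 at −0.688 and miR-5100 at −0.571. Spike scaling replaces quantile normalisation by 1 factor per array, which lowers every unscaled log2 difference by the same amount. The epithelial median thus went from 0.168 with no scaling to −0.799, and the leukocyte median from 0.267 to −0.700. These reversals follow from that shared shift and are no result about single miRNAs. Why the spike spots were brighter stays open. Subtraction of the background around each spot gave −0.006 (intestinal), −0.076 (leukocyte), −1.50 for miR-690, 1.28 for miR-714, 0.230 for miR-92a-2-5p and 0.109 for miR-5623-5p, and the cause was not tested. With each single-factor scaling the percentile was 88.1 for the intestinal and 96.1 for the miR-30 list, and 99.7 for the epithelial and 98.2 for the miR-15/16 list. These scalings share their percentiles by construction and count as 1 result. After subtraction of the background around each spot, 0 of the 5 higher and 1 of the 10 lower miRNAs passed 2-fold. Dim miRNAs limit the folds, since the median brightness over blanks was 44.4 and 31.8. No paired analysis was possible because each group has 1 array.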

Other observations

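The miRNAs of the next paragraph were chosen after their values were seen; the tests on arms and neighbouring genes were written before their results.

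Both arms of miR-712, described as derived from ribosomal RNA precursors, were lower on the DSS array, by −0.92 for miR-712-5p and −0.94 for miR-712-3p. In the authors' table miR-712-5p went from 139 to 50.1 and miR-712-3p from 86.3 to 27.4. Both stayed lower under each scaling, of which scaling to the spike controls lowers every unscaled difference. They were at −0.07 and −0.17 after subtraction of the background around each spot. At the locus of the red cell miRNA miR-486, miR-486b-3p differed by −1.21 and miR-486a-3p by 0.65, although the latter was below 0 with median scaling (−0.19), 75th percentile scaling over all probes (−0.18), no scaling (−0.28) and scaling to the spike controls (−1.25). miR-451b differed by −0.54 where miR-451a differed by 0.73. With scaling to the spike controls miR-451b was at −1.91 and miR-451a at −0.39.

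If a hairpin's transcript changed as a whole, its arms would move together. Across 267 hairpins with both arms measured on both arrays, Pearson's r between the arms' log2 differences was 0.11, at the 96.6 percentile of random pairings, whose central 95% ran from −0.12 to 0.12. Likewise, a shared change of cluster transcripts would tie neighbours together. Across 168 pairs of 117 miRNAs whose genes lie within 10000 bases, r was 0.07, at the 88.1 percentile, with a random range from −0.14 to 0.14. The bound set beforehand would have read these values as the absence of a shared change; that bound was wrong, because a value inside the random range shows neither its presence nor its absence. The hypothesis remains open for both, and miRNAs are not independent replicates.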
